A study of Arabidopsis thaliana with 16 samples.

How the data were processed

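Transcript levels were measured with 1-colour Affymetrix ATH1 arrays in leaves of 4-week-old Arabidopsis thaliana, grown at 20 °C and 65% relative humidity under a light period of 18 h and a night of 6 h, per the labels. RNA was isolated with a Qiagen kit and labelled with biotin in a one-cycle protocol, per the labels' protocols. The deposited values are linear intensity values, 1 signal per probe set and array, summarised with MAS5 in GCOS per the submitters' processing notes; the versions of both are not given in the sources used here. The values show that each array had been scaled to a common mean of signals taken without the lowest and highest 2%. They ran from 0.0236 to 18429.6 units, and all lay above 0.

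The 16 arrays were grouped by the genotype and treatment in their labels into 8 groups of 2. The title of the second array of sid2 after avrB names both replicate numbers, and it was taken as the second array because the other holds the number 1. Of 22810 probe sets, the 64 control probe sets were left out, and so were the dimmest 40% of the others by mean log2 signal over all arrays, those under 20.2 units. The filter uses the mean of all arrays, so a gene with a high signal in 1 group and little elsewhere can fall below it. It left 13647 probe sets. In the annotation used, 13513 probe sets carry 1 gene, 503 carry several and 8730 carry none; 13436 of the first kind were matched to a locus of the TAIR annotation, for 13286 genes. Genes without a matched probe set, among them GSNOR1 and the isochorismate synthase gene, were not analysed here.

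Signals were taken to log2 without a pseudocount, keeping the deposited scaling. One model of 8 group means over all 16 arrays was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend of the variance on the mean), which leaves 8 residual degrees of freedom. Its moderated test was two-sided. Adjusted p-values are Benjamini-Hochberg values within a comparison, and a probe set was called at adjusted p under 0.05 and a log2 difference of at least 1 in size. The 15 comparisons were avrB against untreated in each genotype, each mutant against Col-0 in either state, the difference between each mutant's response and that of Col-0, and atgsnor1-3 against atgsnor1-1 in either state. The number of arrays limits the precision.

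Gene lists were tested with limma's camera, with a preset correlation between genes of 0.01 and, as an alternative, a correlation estimated from the data, where at least 3 members were tested. Of 29 lists fixed in advance, 5 had that many tested members. Adjusted p-values of lists are Benjamini-Hochberg values within a comparison. Lists, comparisons, thresholds and alternatives were fixed before the data were examined; gene families taken by symbol were added after the gene names, but before any values, had been seen. For lists fixed in advance, a second adjustment ran over the list alone.

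Genes are named by a rule. The targeted genes come first. In each comparison, up to 8 genes of largest rise and 8 of largest fall qualify among called probe sets that carry 1 gene and in which every array of the one group lies beyond every array of the other; for a difference between responses, the 8 largest of each sign among called probe sets qualify. Of each list described, up to 4 called members of largest change qualify, and members whose known role bears on the list, given as values only. The text gives a part of these genes, chosen for a known role or a large change.

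Overlaps of lists were set against the number that independent lists of the same sizes would share. For comparisons with the same Col-0 arrays, the correlation and covariance that common arrays alone produce were taken from 100 simulated draws with no effect. These draws gave each gene the same spread in every group. The fit, the test of a difference between responses and the list test were tested on simulated data. In simulated data with the size of this design, 67.2%, 82.1% and 98.5% of genes changed by a log2 of 1.5, 2 and 3 were called in a comparison of 2 groups, and 38.8%, 68.7% and 84.8% in a test of the difference between responses. Of 13447 unchanged genes, 3 were called, and 1.5% of lists without an effect had a camera p under 0.05. The simulated genes varied independently of each other, so this percentage does not cover lists of correlated genes.

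The alternatives were quantile normalization, no filter, a filter on the dimmest 60%, a pseudocount of 9.48 units (the 25th percentile of all signals), a variance without a trend, the replicate number as a term, only the compared groups in the fit, and each array of the compared groups left out in turn. Without 1 array, the lone remaining array of its group is assumed to vary like the other groups, with 7 residual degrees of freedom. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.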

Results

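Transcript levels were measured in leaves of 4-week-old Arabidopsis thaliana plants with the Affymetrix ATH1 array, which holds 22810 probe sets. The 16 arrays fell into 8 groups of 2. The wild type Col-0 and the mutants atgsnor1-1, atgsnor1-3 and sid2 were each sampled untreated and 6 h after avrB. AvrB is an effector of the bacterium Pseudomonas syringae that plants with the resistance protein RPM1 recognise. GSNOR1 encodes S-nitrosoglutathione reductase, which lowers the level of S-nitrosoglutathione. The allele atgsnor1-3 is known as a loss-of-function line and atgsnor1-1 as a line with raised reductase activity, while sid2 lacks the isochorismate synthase that makes most pathogen-induced salicylic acid. Untreated leaves served as the control for avrB, so each response below also holds whatever the inoculation itself did. The labels give a time for the avrB leaves only. Each response may therefore also hold any difference in the time of day of harvest.

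The median signal per array lay between 33.1 and 40.9 units, and 33.7% to 40.6% of all probe sets per array lay below 20.2 units, the level under which probe sets were left out. The correlation across probe sets between the arrays of a group lay between 0.920 and 0.972; probe sets are not independent replicates. In 4 arrays the closest other array belonged to another group. Both untreated Col-0 arrays lay closest to an untreated atgsnor1-1 array, array 1 of untreated atgsnor1-3 to array 1 of untreated sid2, and array 2 of atgsnor1-1 after avrB to array 1 of Col-0 after avrB. The number of arrays limits the precision, and the labels do not say whether the arrays of a group come from separate plants. The p-values therefore measure only the spread between these samples, which may be technical. GSNOR1 and the isochorismate synthase gene were not analysed here, so the genotype labels were not checked against the targeted genes.

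Below, a gene is called when the adjusted p of limma is under 0.05 and the log2 difference is at least 1 in size. Differences are log2 values ± SE from limma and signals are means ± SD, each with n = 2 arrays per group. In every called difference named here, except those between responses, both arrays of the one group lay beyond both arrays of the other. Where leaving out 1 array ended the call of a gene whose difference is given, the array is named with the value or range of values without it, either an adjusted p or a log2 difference whose size is under 1. Signals under 20.2 units lie near background, so large differences from such groups give a direction more firmly than a size. Counts run over 13647 tested probe sets, of which 7332 carry 1 named locus.

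The first comparison asked what avrB changed in Col-0. After 6 h, AT2G43620, of the chitinase family, rose from 87.9 ± 1.95 to 3638 ± 28.5 signal units, a difference of 5.37 ± 0.53 (limma adjusted p = 3.49e-06). AT2G38240, an oxoglutarate-dependent dioxygenase, rose from 43.2 ± 6.24 to 3258 ± 559.7 units, by 6.24 ± 0.43 (limma adjusted p = 9.7e-08). The basic helix-loop-helix gene AT1G10585 rose by 7.15 ± 0.82, AT4G22470 by 5.60 ± 0.34, the glycosyltransferase gene UGT76E12 (AT3G46660) by 5.53 ± 0.88 and AT4G20860, of the berberine bridge enzyme family, by 5.25 ± 0.64. Among the strongest falls, AT3G15570 fell from 70.1 ± 9.77 to 5.70 ± 0.102 units, a difference of -3.61 ± 0.65. ATKDSA2 (AT1G16340), an enzyme of cell wall sugar synthesis, changed by -3.55 ± 0.48, and QQS (AT3G30720), a gene known to affect leaf starch, by -3.01 ± 0.48. In total 1690 genes were called, 998 higher and 692 lower, and the median over all genes was -0.12.

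The list of salicylic acid marker genes, fixed in advance, had 3 tested members, and all of them rose in Col-0: the glycosyltransferase UGT76B1 (AT3G11340) by 4.23 ± 0.87, the glutaredoxin GRX480 (AT1G28480) by 2.32 ± 0.29 and the transcription factor WRKY53 (AT4G23810) by 1.25 ± 0.27. Most genes of this list, PR1 among them, were not tested, so the 3 stand for a small part of it. Without array 1 of untreated Col-0, WRKY53 stood at 0.98 and lost its call. The count is also 3 when adjusted over the list alone, and limma's camera test gave adjusted p = 0.00131, and adjusted p = 0.0402 with an estimated correlation. Of 9 tested photosynthesis genes 5 fell, a count that is the same when adjusted over the list alone, among them LHCB4.2 (AT3G08940), a light-harvesting protein, at -1.60 ± 0.19, LHCB4.3 (AT2G40100) at -1.25 ± 0.29, PSBY (AT1G67740) at -1.08 ± 0.15 and phosphoribulokinase PRK (AT1G32060) at -1.02 ± 0.16. The calls of PSBY and PRK were lost without array 1 of untreated Col-0 (log2 differences of -0.97 and -0.89), without array 1 of Col-0 after avrB (-0.97 and -0.99) and with quantile normalization. Without either of these arrays, 2 of the 5 genes kept their call. The list gave adjusted p = 1.78e-05 by camera, and adjusted p = 0.124 with an estimated correlation. Of 3 chlorophyll synthesis genes, CHLM (AT4G25080) fell by 1.42 and PORB (AT4G27440) by 1.07 on the log2 scale, the latter call being lost without array 1 of untreated Col-0 (log2 difference of -0.94), and GSA1 (AT5G63570) stood at 0.24 ± 0.15; 2 pass when adjusted over the list alone, and the camera adjusted p was 0.138. The endoplasmic reticulum chaperone list had 3 tested members, the calreticulin gene CRT1b, the co-chaperone gene ATERDJ3B and BZIP60, which encodes not a chaperone but a transcription factor of the unfolded protein response. They and 4 tested flavonoid genes had no call (camera adjusted p = 0.635 and 0.84; 0 when adjusted over the list alone). Members of lists with fewer than 3 tested genes carry no list test. Among them, the senescence-linked factor WRKY6 (AT1G62300) rose by 3.74 ± 0.38, the lignin-pathway reductase CCR2 (AT1G80820) by 3.88 ± 0.50, the calmodulin-like CML38 (AT1G76650) by 3.18 ± 0.62, the zinc finger factor STZ (AT1G27730) by 2.12 ± 0.20, the receptor-like kinase BIK1 (AT2G39660) by 1.76 ± 0.19, SGT1A (AT4G23570), a co-chaperone of resistance proteins, by 1.52 ± 0.20 and AT2G04400, of tryptophan synthesis, by 1.29 ± 0.19. The glucosinolate genes AT2G31790 and BCAT4 (AT3G19710) stood lower at -2.18 ± 0.23 and -1.65 ± 0.21.

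The same comparison in the mutants asked what avrB changed in each of them. In atgsnor1-1, 2610 genes were called, 1171 higher and 1439 lower. UGT76E12 rose by 7.67 ± 0.88, AT1G10585 by 7.14 ± 0.82, UGT76B1 by 6.81 ± 0.87 to 1767 ± 278 units (limma adjusted p = 1.8e-05), and AT4G12500 by 6.14 ± 0.61. STOMAGEN (AT4G12970), a peptide that promotes stomata, changed by -4.50 ± 0.92, and EXPA8 (AT2G40610), an expansin that loosens cell walls, by -3.73 ± 0.42, from 330.4 ± 28.7 to 24.9 ± 1.89 units (limma adjusted p = 5.43e-06). The 3 salicylic acid markers rose (3 when adjusted over the list alone; camera adjusted p = 0.000137, and adjusted p = 0.0178 with an estimated correlation). Of 9 photosynthesis genes 4 fell (4 when adjusted over the list alone; camera adjusted p = 7.64e-05, and adjusted p = 0.145 with an estimated correlation), and 3 kept their call without array 2 of untreated atgsnor1-1 or array 2 after avrB. CHLM and PORB fell too, at -1.62 ± 0.18 and -1.74 ± 0.22 (2 when adjusted over the list alone; camera adjusted p = 0.0319, and adjusted p = 0.145 with an estimated correlation). Of the chaperone list, the transcription factor gene BZIP60 (AT1G42990) rose by 1.29 ± 0.17 (1 when adjusted over the list alone; camera adjusted p = 0.0196, and adjusted p = 0.17 with an estimated correlation).

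In atgsnor1-3, 4767 genes were called after avrB, 2041 higher and 2726 lower. AT3G01830, an EF-hand calcium-binding protein, rose by 10.33 ± 0.26, from 1.12 ± 0.455 to 1380.2 ± 2.91 units (limma adjusted p = 3.82e-13). AT1G57630, with a TIR domain, rose by 9.65 ± 0.38, from 1.98 ± 1.57 to 1315 ± 94.1 units (limma adjusted p = 2.81e-11). Both stood near background before treatment. The small heat shock protein AT5G51440 rose by 7.85 ± 0.84, CCR2 by 7.64 ± 0.50, CML38 by 6.81 ± 0.62 and STZ by 4.58 ± 0.20. AT3G15570 changed by -7.30 ± 0.65, EXPA8 by -5.91 ± 0.42, the homeobox factor HAT2 (AT5G47370) by -5.25 ± 0.33 and AT1G19960 by -5.21 ± 0.26, from 433 ± 77.1 to 12.3 ± 5.64 units (limma adjusted p = 2.17e-10). The 3 salicylic acid markers rose (3 when adjusted over the list alone; camera adjusted p = 0.00203, and adjusted p = 0.048 with an estimated correlation). Of 9 photosynthesis genes 5 fell (5 when adjusted over the list alone; camera adjusted p = 0.00203, and adjusted p = 0.24 with an estimated correlation). Without array 2 of untreated atgsnor1-3 or array 2 after avrB, 3 of the 5 kept their call, as LHCB4.1 (log2 differences of -0.76 and -0.83) and PSAE-1 (-0.99 and -0.99) lost theirs, and without array 1 of untreated atgsnor1-3 PSBY did (-0.96). With quantile normalization LHCB4.1, PSAE-1 and PSBY all lost their call, at -0.18, -0.42 and -0.58. The defensin PDF1.2 (AT5G44420) changed by -2.48 ± 0.77 and WES1 (AT4G27260), an auxin-conjugating enzyme, by -2.90 ± 0.79. PDF1.2 lost its call without array 2 of untreated atgsnor1-3 or array 2 after avrB (limma adjusted p = 0.248 and 0.0541). WES1 lost it without array 1 of atgsnor1-3 after avrB (limma adjusted p = 0.114) and with only the compared groups in the fit. Of the chaperone list, BZIP60 rose by 3.19 ± 0.17 and the calreticulin CRT1b (AT1G09210) fell, at -1.26 ± 0.24 (2 when adjusted over the list alone; camera adjusted p = 0.492).

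In sid2, 3063 genes were called after avrB, 1485 higher and 1578 lower. AT3G01830 rose by 9.29 ± 0.26, AT4G39670 by 9.06 ± 0.39, the xyloglucan-modifying XTH18 (AT4G30280) by 8.20 ± 0.73 and AT1G05340 by 7.86 ± 0.36, each from a mean signal under 3 units. CCR2 rose by 6.72 ± 0.50. PDF1.2 fell from 388 ± 85.6 to 21.0 ± 2.19 units, a difference of -4.19 ± 0.77 (limma adjusted p = 0.000405), and AT1G19960 changed by -4.86 ± 0.26. The 3 salicylic acid markers rose here as well: UGT76B1 by 5.04 ± 0.87, from 4.16 ± 2.65 to 123 ± 25.4 units, GRX480 by 3.40 ± 0.29 and WRKY53 by 2.43 ± 0.27 (3 when adjusted over the list alone; camera adjusted p = 0.0011, and adjusted p = 0.0375 with an estimated correlation). Each rose by at least as much as in Col-0, so their rise alone is no measure of salicylic acid. Of 9 photosynthesis genes 3 fell (3 when adjusted over the list alone; camera adjusted p = 0.000566, and adjusted p = 0.174 with an estimated correlation). BZIP60 rose by 2.18 ± 0.17 and the co-chaperone ATERDJ3B (AT3G62600) by 1.31 ± 0.19 (2 when adjusted over the list alone; camera adjusted p = 0.00884, and adjusted p = 0.174 with an estimated correlation).

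The responses of the 4 genotypes shared many genes. In all 4 genotypes 669 genes were called higher and 401 lower. Col-0 and atgsnor1-1 shared 765 higher genes, where independent lists would share 85.6, and 451 lower genes, where they would share 73.0. Col-0 and atgsnor1-3 shared 816 higher and 556 lower genes against 149 and 138 for independent lists. Col-0 and sid2 shared 834 higher and 503 lower genes against 109 and 80.0. These pairs of responses have no array in common. Across genes, which are not independent replicates, the responses of Col-0 and the mutants correlated with r = 0.792 for atgsnor1-1, 0.736 for atgsnor1-3 and 0.816 for sid2. Among genes called in both, the median ratio of the mutant's log2 response to that of Col-0 was 1.17 in atgsnor1-1, 1.56 in atgsnor1-3 and 1.31 in sid2.

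**Figure D1:**
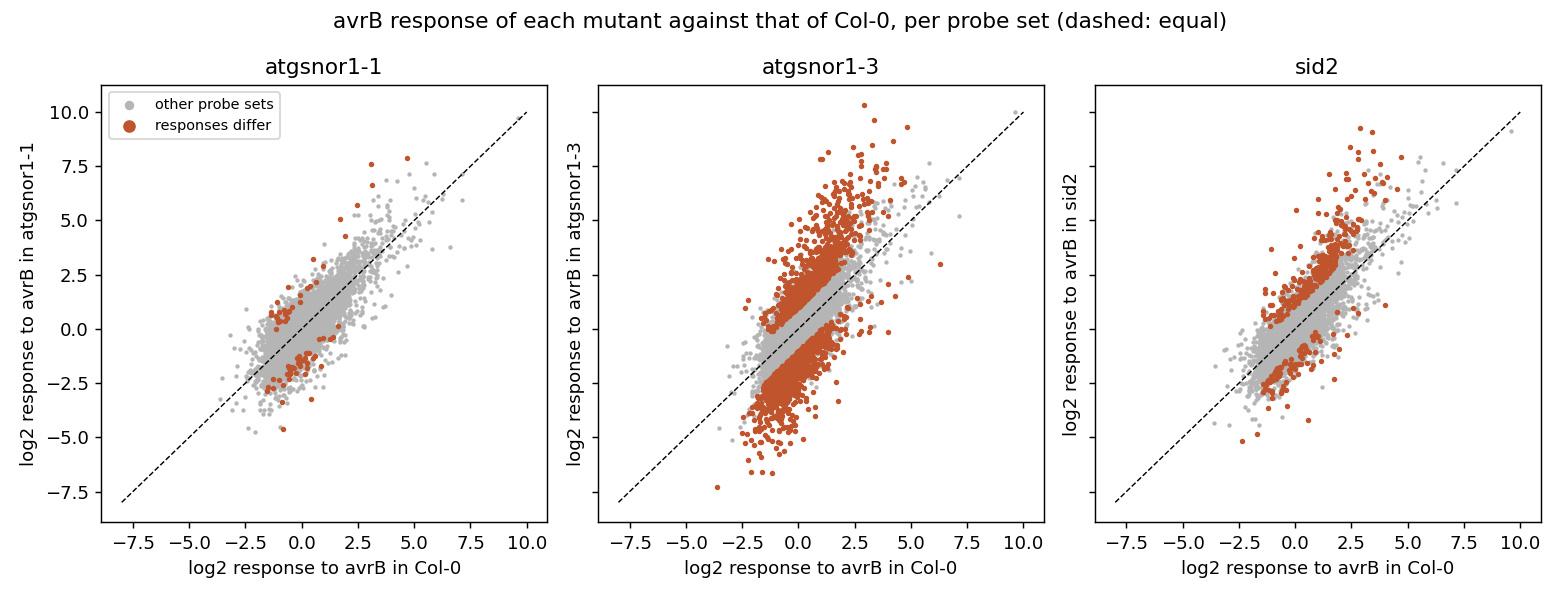
Each point is 1 of 13647 probe sets, with its log2 response to avrB in Col-0 on the x axis and that in atgsnor1-1, atgsnor1-3 or sid2 on the y axis. Coloured points are the 76, 2055 and 355 probe sets whose responses differ by the test of the difference, and the dashed line marks equal responses.

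The next comparison asked how untreated mutant leaves differed from untreated Col-0. In untreated atgsnor1-3 leaves AT5G55450, of the lipid transfer protein family, stood at 13.7 ± 10.4 units against 1576 ± 132 in Col-0, a difference of -7.10 ± 0.39 (limma adjusted p = 2.71e-09). The aspartyl protease gene AT3G51330 stood at 1.80 ± 0.557 against 173 ± 23.3 units, a difference of -6.62 ± 0.29 (limma adjusted p = 2.22e-10). AT3G01830 differed by -6.60 ± 0.26, AT1G76960 by -6.57 ± 0.61, AT1G57630 by -6.42 ± 0.38 and AT5G52760, a heavy-metal-associated domain protein, by -6.26 ± 0.66. Higher in atgsnor1-3 were AT4G29610 at 3.97 ± 0.43 and AT5G47455 at 3.39 ± 0.50, both from under 10 units in Col-0. In total 1199 genes were called, 312 higher and 887 lower. The count was 782 with only the compared groups in the fit.

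The 3 salicylic acid markers were lower in untreated atgsnor1-3: GRX480 at -4.07 ± 0.29, UGT76B1 at -3.67 ± 0.87 and WRKY53 at -2.99 ± 0.27 (3 when adjusted over the list alone; camera adjusted p = 2.43e-05, and adjusted p = 0.0104 with an estimated correlation). The 3 members of the endoplasmic reticulum chaperone list were lower too: ATERDJ3B at -2.07 ± 0.19, CRT1b at -1.69 ± 0.24 and BZIP60 at -1.56 ± 0.17 (3 when adjusted over the list alone; camera adjusted p = 2.43e-05, and adjusted p = 0.0462 with an estimated correlation). SGT1A at -2.16 ± 0.20, the immunophilin AT5G48570 at -1.62 ± 0.29, AT5G52810 at -2.24 ± 0.20 and CCR2 at -2.50 ± 0.50 were lower as well. Of 9 photosynthesis genes 1, LHCB4.3 (AT2G40100), was lower at -1.61 ± 0.29 (1 when adjusted over the list alone; camera adjusted p = 0.326). The call of UGT76B1 was lost without array 2 of untreated Col-0 or array 1 of untreated atgsnor1-3 (limma adjusted p = 0.0727 and 0.052). With only the compared groups in the fit, UGT76B1 and CCR2 were not called, nor was CCR2 with a pseudocount.

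Untreated sid2 leaves differed from Col-0 in 808 genes, 267 higher and 541 lower. AT3G01830 stood at -6.04 ± 0.26 (limma adjusted p = 1.57e-09), AT5G08240 at -5.51 ± 0.37, AT3G13610, an enzyme of scopoletin synthesis, at -5.13 ± 0.48, AT5G55450 at -4.13 ± 0.39 and the chitinase CHI (AT2G43570) at -4.11 ± 0.23, from 933 ± 214 units in Col-0 to 53.7 ± 10.7 in sid2 (limma adjusted p = 1.06e-08). Higher in sid2 were AT2G20670 at 5.71 ± 0.99, ORA47 (AT1G74930), a jasmonate-responsive transcription factor, at 3.25 ± 0.32 and the expansin-like EXLA1 (AT3G45970) at 2.73 ± 0.27, from 41.0 ± 13.6 to 269 ± 79.0 units (limma adjusted p = 4.59e-06). The 3 salicylic acid markers were lower, UGT76B1 at -3.70 ± 0.87, GRX480 at -1.98 ± 0.29 and WRKY53 at -1.35 ± 0.27 (3 when adjusted over the list alone; camera adjusted p = 0.000416, and adjusted p = 0.0261 with an estimated correlation). The members of the chaperone list were lower too, ATERDJ3B at -1.96 ± 0.19, CRT1b at -1.71 ± 0.24 and BZIP60 at -1.38 ± 0.17 (3 when adjusted over the list alone; camera adjusted p = 4.75e-06, and adjusted p = 0.0305 with an estimated correlation). The cold-regulated COR15A (AT2G42540) and COR47 (AT1G20440) were higher at 1.15 ± 0.20 and 1.01 ± 0.20. Without array 2 of untreated Col-0, UGT76B1, WRKY53 and COR47 lost their calls (limma adjusted p = 0.102, 0.0569 and 0.0638), and so did COR15A, at 0.97. UGT76B1 and COR47 also lost theirs without array 1 of untreated sid2 (limma adjusted p = 0.126 and 0.0621), and COR47 with quantile normalization or a pseudocount.

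**Figure D2:**
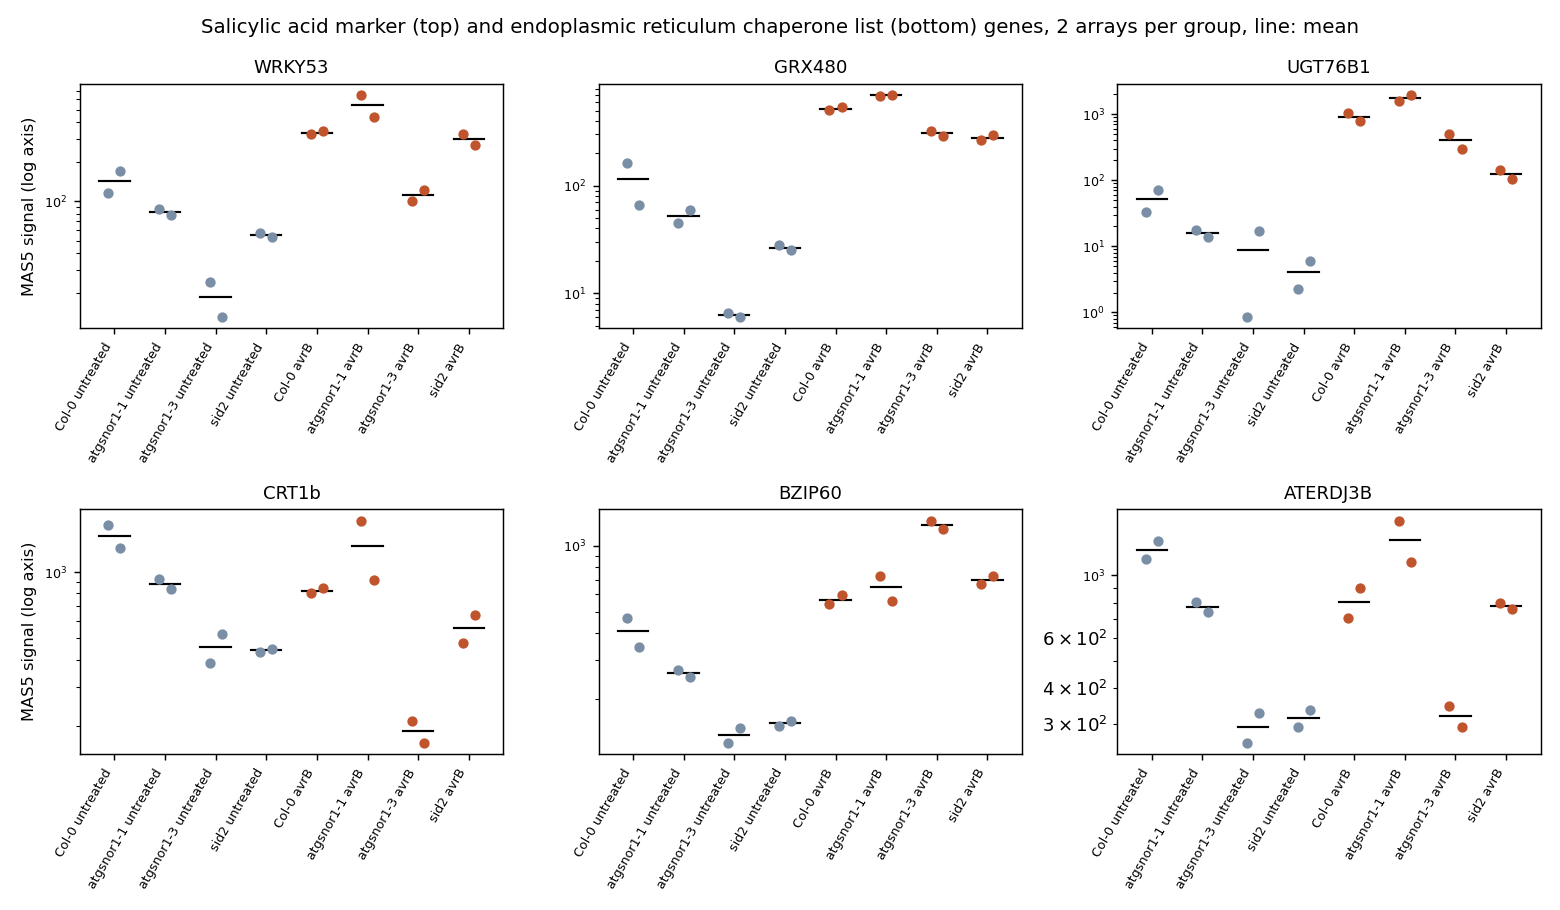
MAS5 signal in units (log axis) of 3 salicylic acid marker genes (top) and 3 members of the endoplasmic reticulum chaperone list (bottom; BZIP60 is a transcription factor gene) in the 8 groups, where points are arrays and lines are group means. In all 6 panels both arrays of untreated atgsnor1-3 lie below both arrays of untreated Col-0.

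The lists of untreated atgsnor1-3 and sid2 overlapped. Of the genes lower than in Col-0, 443 were lower in both mutants, where independent lists would share 35.2, and 88 were higher in both against 6.10. Both comparisons use the same Col-0 arrays. The correlation across genes was 0.741, against 0.501 in 100 simulated draws with no effect, and the covariance 0.406 against 0.0566 simulated, a difference of 0.349. The draws gave each gene the same spread in every group, so they may understate what the common arrays add. When sid2 was set against Col-0 and atgsnor1-3 against atgsnor1-1, with no array in common, 351 genes were lower in both against 26.8 for independent lists. When sid2 was set against atgsnor1-1 and atgsnor1-3 against Col-0, 279 were, against 19.8. The covariance with no array in common was 0.248 in the former setting and 0.255 in the latter, below 0.406. Set directly against each other, untreated atgsnor1-3 and sid2 differed in 307 genes, 57 higher and 250 lower in atgsnor1-3.

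Untreated atgsnor1-1 leaves differed from Col-0 in 20 genes, 12 higher and 8 lower. AT1G04040 stood at 638 ± 106 units against 225 ± 55.0 in Col-0, a difference of 1.51 ± 0.25 (limma adjusted p = 0.0257). AT1G20070 at -1.54 ± 0.24 and AT3G01830 at -1.57 ± 0.26 were lower. AT5G47455 at 2.80 ± 0.50, AT4G29610 at 2.59 ± 0.43 and AT1G64700 at 2.56 ± 0.41 were higher, each from under 10 units in Col-0. None of the 3 salicylic acid markers was called, though 1 was lower when adjusted over the list alone (median -1.02; camera adjusted p = 0.000893, and adjusted p = 0.0346 with an estimated correlation). None of the 3 members of the chaperone list was called either (0 when adjusted over the list alone; median -0.66; camera adjusted p = 9.82e-05, and adjusted p = 0.0575 with an estimated correlation). All 3 untreated mutants are set against the same Col-0 arrays. These lists, lower in each mutant, are therefore not independent results, and high values in those arrays could add to each. The count rested on single arrays: it was 83 without array 1 of untreated Col-0, 12 and 7 without array 1 or 2 of untreated atgsnor1-1, and each called gene of this paragraph lost its call without array 1 or 2 of untreated atgsnor1-1. AT1G04040, AT1G20070, AT3G01830 and AT5G47455 lost theirs without array 2 of untreated Col-0 as well. Over these left-out arrays, the limma adjusted p ran over 0.0601 to 0.213 for AT1G04040, 0.0739 to 0.0911 for AT1G20070, 0.0783 to 0.197 for AT3G01830, 0.125 to 0.203 for AT5G47455, 0.135 to 0.166 for AT4G29610 and 0.0857 to 0.144 for AT1G64700. The count was 10 with no filter on dim probe sets, 6 with the lowest 60% left out and 6 with only the compared groups in the fit, and with a pseudocount the direction turned to 11 higher and 14 lower.

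In all 3 mutants 7 genes were higher than in untreated Col-0, namely AT5G49560, AT5G47455, AT3G59670, AT4G29610, AT1G73760, AT1G64700 and AT1G22900, and 4 were lower, of which AT3G01830 is named. The 7 higher genes are named because of their small number, after their values were seen. Each lost its call in atgsnor1-1 without array 1 or 2 of untreated atgsnor1-1 (limma adjusted p = 0.0574 to 0.276). Without array 2 of untreated Col-0, AT5G49560, AT5G47455, AT1G73760 and AT1G22900 lost it as well (limma adjusted p = 0.0563 to 0.140), and without array 1 AT3G59670 did (limma adjusted p = 0.058). Their median log2 difference over the 3 mutants was 2.56 untreated and -0.03 after avrB.

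After avrB, the comparison with Col-0 asked which levels differed between genotypes at 6 h. In atgsnor1-3, AT2G41730 stood at 2159.8 ± 294 units against 85.6 ± 6.45 in Col-0, a difference of 4.65 ± 0.43 (limma adjusted p = 1.2e-06). AT2G21640, known as a gene induced by oxidative stress, stood at 1149 ± 199 against 49.8 ± 1.81 units, a difference of 4.52 ± 0.39 (limma adjusted p = 6.96e-07). AT5G51440 was higher by 4.47 ± 0.84, AT5G16980 by 4.08 ± 0.89, the dioxygenase gene AT5G43450 by 3.80 ± 0.23, CML38 by 2.07 ± 0.62 and STZ by 1.66 ± 0.20. Lower in atgsnor1-3 were AT5G55450 at -7.99 ± 0.39, AT1G76960 at -7.87 ± 0.61, the lectin gene AT5G03350 at -5.97 ± 0.26, from 2613 ± 312 units in Col-0 to 41.4 ± 1.12 (limma adjusted p = 3.33e-10), and UGT72E1 (AT3G50740) at -4.78 ± 0.35. In total 1784 genes were called, 589 higher and 1195 lower. Of the salicylic acid markers WRKY53 was lower at -1.60 ± 0.27, while GRX480 at -0.77 ± 0.29 and UGT76B1 at -1.23 ± 0.87 were not called (1 when adjusted over the list alone; camera adjusted p = 0.248). The chaperone list split: the transcription factor gene BZIP60 was higher at 1.14 ± 0.17, and the chaperone genes CRT1b at -2.13 ± 0.24 and ATERDJ3B at -1.33 ± 0.19 were lower (3 when adjusted over the list alone; camera adjusted p = 0.329). WES1 at -3.03 ± 0.79, PDF1.2 at -2.30 ± 0.77, BCAT4 at -1.68 ± 0.21 and AT2G31790 at -1.37 ± 0.23 were lower. CML38 and PDF1.2 lost their calls without any 1 of the 4 compared arrays, array 1 and array 2 of Col-0 and of atgsnor1-3 after avrB (limma adjusted p = 0.0786 to 0.115 and 0.11 to 0.153). WES1 lost it without array 1 or 2 of Col-0 or array 1 of atgsnor1-3 after avrB (limma adjusted p = 0.0523 to 0.14).

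**Figure D3:**
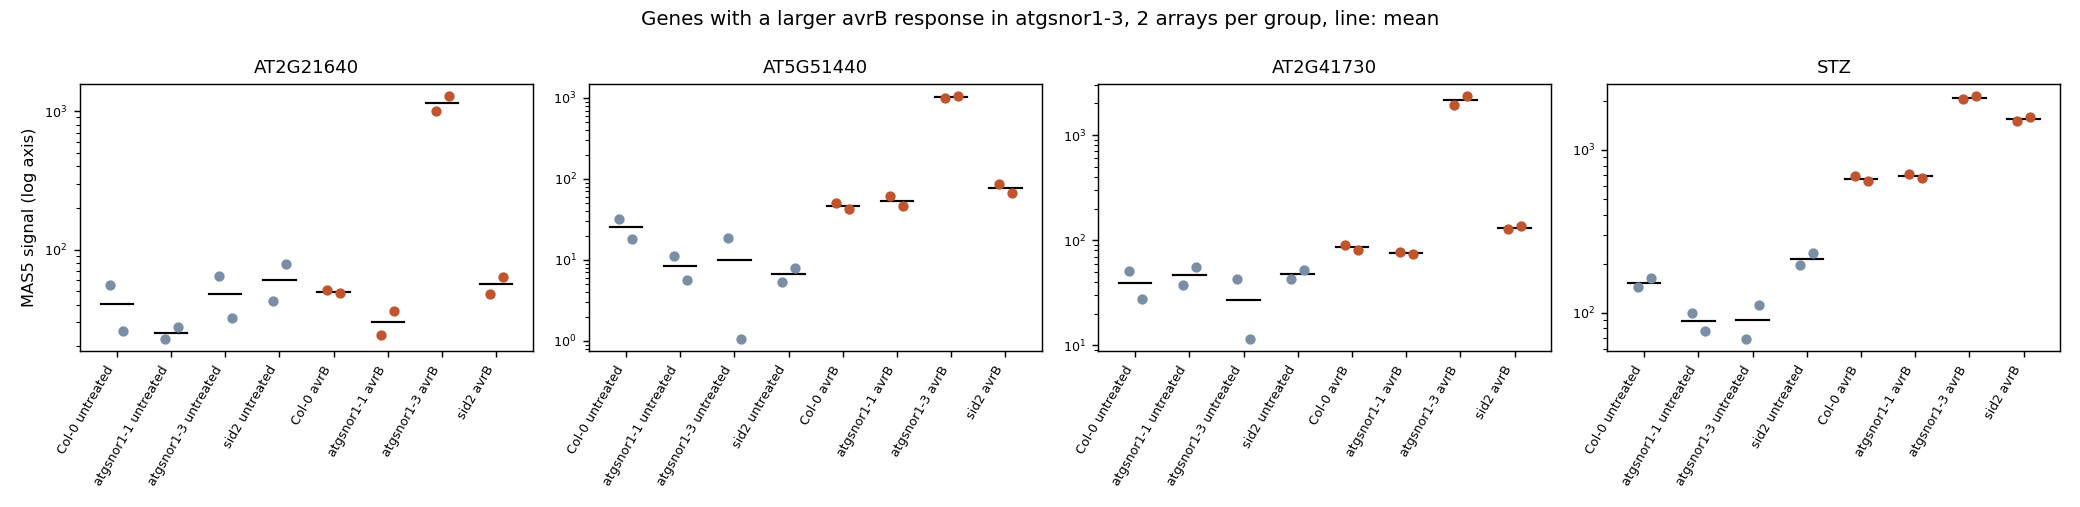
MAS5 signal in units (log axis) of AT2G21640, AT5G51440, AT2G41730 and STZ in the 8 groups, where points are arrays and lines are group means. After avrB, the atgsnor1-3 means are 1149, 1029, 2159.8 and 2097 units, against 49.8, 46.7, 85.6 and 664 in Col-0.

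In sid2 after avrB, 205 genes differed from Col-0, 73 higher and 132 lower. AT3G52870 stood at 577 ± 68.0 units against 17.5 ± 11.4 in Col-0, a difference of 5.21 ± 0.41 (limma adjusted p = 1.17e-06). AT5G03350 at -5.04 ± 0.26, AT1G76960 at -4.67 ± 0.61, AT1G19960 at -3.58 ± 0.26 and AT5G55450 at -2.88 ± 0.39 were lower (limma adjusted p = 1.36e-08, 0.000423, 4.08e-07 and 0.000622). STZ was higher at 1.22 ± 0.20. None of the salicylic acid markers was called, UGT76B1 standing at -2.89 ± 0.87, and 1 was lower when adjusted over the list alone (camera adjusted p = 0.0626). None of the chaperone list was called (0 when adjusted over the list alone; camera adjusted p = 0.875). The count was 122 and 102 without array 1 or 2 of Col-0 after avrB, 94 without array 2 of sid2 after avrB, and 374 with only the compared groups in the fit. Between atgsnor1-3 and sid2 after avrB, 117 lower genes were shared against 11.6 for independent lists and 41 higher against 3.15. The correlation across genes was 0.544 against 0.500 simulated for the shared Col-0 arrays, and the covariance 0.212 against 0.0565 simulated. With no array in common, 116 lower genes were shared against 11.8, and the covariance was 0.198. Set directly against each other after avrB, the mutants differed in 1209 genes, 344 higher and 865 lower in atgsnor1-3.

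In atgsnor1-1 after avrB, 22 genes differed from Col-0, 7 higher and 15 lower. AT3G52870 stood at 334 ± 86.8 units against 17.5 ± 11.4, a difference of 4.40 ± 0.41 (limma adjusted p = 0.000166), and was also the 1 gene called higher in all 3 mutants after avrB, at 3.40 ± 0.41 in atgsnor1-3. These comparisons share the Col-0 arrays, so they are not independent. Against untreated Col-0, AT3G52870 stood at 1.98, 1.39 and 1.73 in untreated atgsnor1-1, atgsnor1-3 and sid2. In each of these mutants both untreated arrays lay above both untreated Col-0 arrays, so its higher level is not particular to avrB. It is not among the genes called in every untreated mutant, which does not exclude a call in some of them. AT5G62360 was lower at -1.42 ± 0.17 (limma adjusted p = 0.00242). The dehydrin genes COR47 and LTI30 (AT3G50970) were lower at -1.16 ± 0.20 and -1.13 ± 0.21, calls that were lost without array 1 or 2 of Col-0 or array 1 of atgsnor1-1 (limma adjusted p = 0.123 to 0.298 and 0.271 to 0.403). The salicylic acid markers had no call (0 when adjusted over the list alone; median 0.68; camera adjusted p = 0.0469, and adjusted p = 0.175 with an estimated correlation), and the chaperone list none (0 when adjusted over the list alone; median 0.61; camera adjusted p = 0.00739, and adjusted p = 0.175 with an estimated correlation). The count was 8 and 5 without array 1 or 2 of Col-0 after avrB, and 11 and 113 without array 1 or 2 of atgsnor1-1 after avrB. It was 12 with no filter, 11 with a variance without a trend, 11 with the replicate block, 63 with only the compared groups in the fit, and a pseudocount gave 14 higher and 15 lower genes.

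A test of the difference between responses asked where a mutant answered avrB unlike Col-0. In atgsnor1-3, 2055 genes differed, 926 with a more positive and 1129 with a more negative response. AT2G21640 had a response larger by 4.26 ± 0.56, AT5G51440 by 6.91 ± 1.19 and AT2G41730 by 5.42 ± 0.61 (limma adjusted p = 7.76e-05, 0.000791 and 2.17e-05). Their untreated levels in atgsnor1-3 against Col-0 stood at 0.26 ± 0.39, -2.44 ± 0.84 and -0.77 ± 0.43 and were not called (limma adjusted p = 0.698, 0.0575 and 0.244). AT3G01830 at 7.44 ± 0.36 and AT1G57630 at 6.28 ± 0.53 also had a larger response, from a lower untreated level. More negative were HAT2 at -4.86 ± 0.47 and AT3G20820 at -4.29 ± 0.51 (limma adjusted p = 7.04e-06 and 3.71e-05). Of the 926 genes, 433 (46.8%) were lower than Col-0 when untreated, 313 (33.8%) were higher after avrB, 51 were both and 231 (24.9%) neither. Of the 1129 genes, 648 (57.4%) were lower than Col-0 after avrB and 139 (12.3%) were higher when untreated. The difference between responses is the difference after avrB minus that when untreated, from the same arrays. These shares therefore divide up that contrast and are no separate test. GRX480 at 3.29 ± 0.41, WRKY53 at 1.39 ± 0.38, BZIP60 at 2.70 ± 0.24, CCR2 at 3.76 ± 0.71, CML38 at 3.62 ± 0.87 and STZ at 2.46 ± 0.28 responded more positively. Of these, GRX480 and WRKY53 were lower than in Col-0 when untreated and did not rise above Col-0 after avrB, where WRKY53 was still called lower. WES1 at -3.52 ± 1.11, BCAT4 at -1.99 ± 0.29, AT2G31790 at -1.71 ± 0.32, PORB at -1.34 ± 0.31 and PRK at -1.09 ± 0.22 responded more negatively. WRKY53 lost its call without array 2 of untreated Col-0, array 1 of Col-0 after avrB or array 2 of atgsnor1-3 in either state (limma adjusted p = 0.0609 to 0.0778). PRK lost it without array 2 of untreated Col-0 or array 2 of atgsnor1-3 after avrB (log2 differences of -0.96 and -0.95). WES1 lost it without array 2 of untreated Col-0, array 1 of atgsnor1-3 in either state or array 1 or 2 of Col-0 after avrB (limma adjusted p = 0.0843 to 0.121).

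In sid2, 355 responses differed from those of Col-0, 262 more positive and 93 more negative. AT3G01830 at 6.39 ± 0.36, AT4G39670 at 5.66 ± 0.55 and AT5G08240 at 5.45 ± 0.53 were more positive (limma adjusted p = 1.3e-07, 2.92e-05 and 2.92e-05), and AT1G19960 at -3.17 ± 0.36 and ORA47 at -2.64 ± 0.45 more negative. Of the 262 genes, 212 (80.9%) were lower than Col-0 when untreated and 15 were higher after avrB. As in atgsnor1-3, these shares divide up the contrast itself. BZIP60 at 1.68 ± 0.24 and ATERDJ3B at 1.92 ± 0.26 were more positive (2 over all genes, 3 when adjusted over the list alone; camera adjusted p = 1.05e-06, and adjusted p = 0.046 with an estimated correlation). The count was 213 and 214 without array 1 or 2 of Col-0 after avrB, 203 without array 1 of sid2 after avrB and 222 with a variance without a trend.

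In atgsnor1-1, 76 responses differed from those of Col-0, 30 more positive and 46 more negative. AT3G29240 at 1.58 ± 0.22 was more positive, and AT1G04040 at -2.50 ± 0.35 and AT5G62360 at -2.01 ± 0.24 were more negative (limma adjusted p = 0.0078, 0.0078 and 0.00474). ATERDJ3B was more positive at 1.38 ± 0.26 (1 of 3 members of the chaperone list over all genes, 2 when adjusted over the list alone; camera adjusted p = 3.51e-05, and adjusted p = 0.0459 with an estimated correlation). Without single arrays the count ran from 1, without array 2 of Col-0 after avrB, to 201, without array 2 of atgsnor1-1 after avrB. AT3G29240 lost its call without array 2 of Col-0 or array 1 of atgsnor1-1 after avrB (limma adjusted p = 0.0511 to 0.0708), and AT1G04040 without array 1 or 2 of Col-0 after avrB (limma adjusted p = 0.0584 to 0.0708). ATERDJ3B lost it without array 2 of untreated Col-0, array 1 or 2 of untreated atgsnor1-1, array 1 or 2 of Col-0 after avrB or array 1 of atgsnor1-1 after avrB (limma adjusted p = 0.0795 to 0.171). Leaving out the other arrays moved the count as well, to 127 and 30 without array 1 or 2 of untreated Col-0, 14 and 26 without array 1 or 2 of untreated atgsnor1-1, 3 without array 1 of Col-0 after avrB and 5 without array 1 of atgsnor1-1 after avrB. It was 42 with no filter, 29 with a variance without a trend, 119 with only the compared groups in the fit, and 65 more positive and 61 more negative with a pseudocount.

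**Figure D4:**
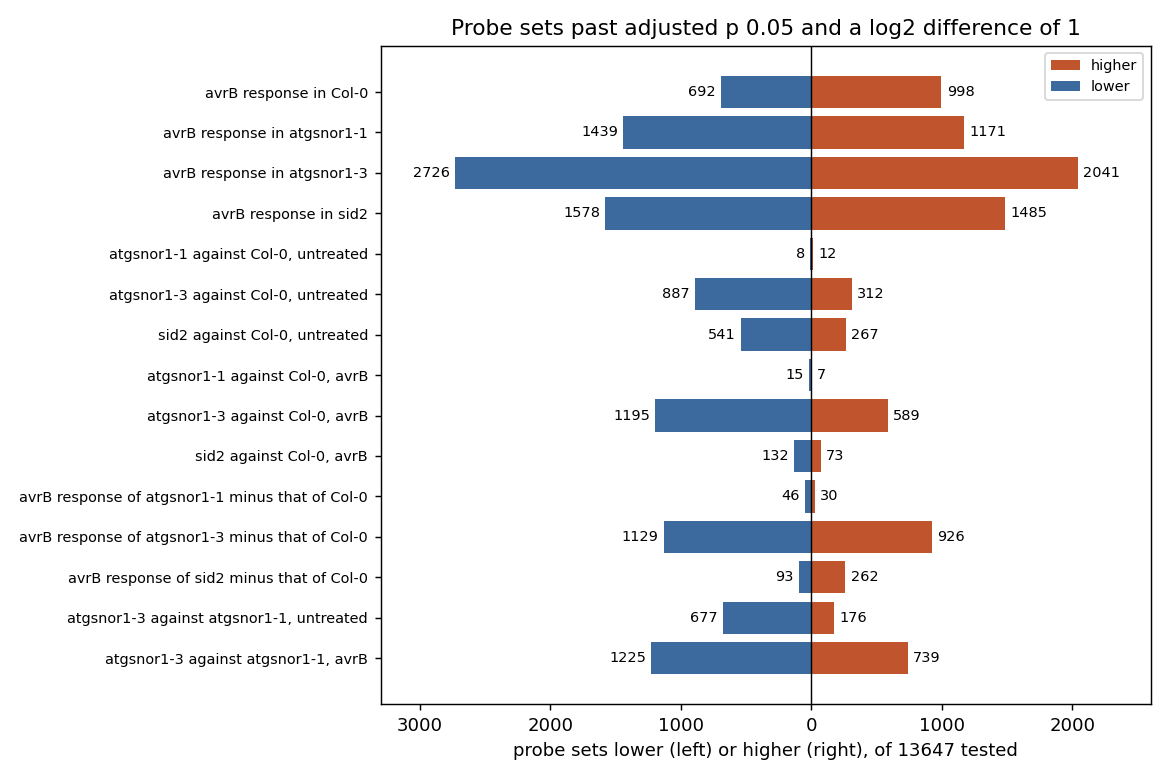
Bars give the number of probe sets called higher (right) or lower (left) in each of the 15 comparisons, of 13647 tested. The avrB response of atgsnor1-3 holds the most, 4767, and untreated atgsnor1-1 against Col-0 the fewest, 20.

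Setting the 2 GSNOR1 alleles against each other asked where lines known for low and for raised reductase activity differ. Untreated, atgsnor1-3 differed from atgsnor1-1 in 853 genes, 176 higher and 677 lower. The glutamate receptor-like channel gene GLR2.7 (AT2G29120) stood at 3.95 ± 0.0430 units in atgsnor1-3 and 129 ± 24.5 in atgsnor1-1, a difference of -5.02 ± 0.21 (limma adjusted p = 1.45e-10). AT5G55450 at -6.69 ± 0.39, AT1G57630 at -6.34 ± 0.38 and AT3G51330 at -6.25 ± 0.29 were lower in atgsnor1-3. GRX480 at -3.05 ± 0.29 and WRKY53 at -2.23 ± 0.27 were lower (2 over all genes, 3 when adjusted over the list alone; camera adjusted p = 0.000335, and adjusted p = 0.019 with an estimated correlation). ATERDJ3B was lower at -1.41 ± 0.19 (1 when adjusted over the list alone; camera adjusted p = 0.000417, and adjusted p = 0.0961 with an estimated correlation). After avrB the alleles differed in 1964 genes, 739 higher and 1225 lower. AT2G21640 at 5.27 ± 0.39, AT2G41730 at 4.82 ± 0.43 and AT5G43450 at 3.73 ± 0.23 were higher, and AT1G76960 at -9.21 ± 0.61, AT5G55450 at -8.28 ± 0.39 and AT5G03350 at -6.64 ± 0.26 lower in atgsnor1-3 (limma adjusted p = 9.83e-08, 7.01e-07, 1.17e-08, 2.16e-08, 5.99e-10 and 7.9e-11). WRKY53 at -2.28 ± 0.27 and GRX480 at -1.18 ± 0.29 were lower (2 over all genes, 3 when adjusted over the list alone; camera adjusted p = 0.0389, and adjusted p = 0.138 with an estimated correlation).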

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

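The differences in response below were tested by a planned comparison, and the count with quantile normalization that weighs the second pattern was planned, with its limit set after the results were seen. The other tests that weigh the 3 patterns were chosen only after the results were seen. What set these results apart is that the test of the difference found a mutant's response to avrB unlike that of Col-0. The responses differed in 76 genes for atgsnor1-1, 2055 for atgsnor1-3 and 355 for sid2. The 76 became 1 without array 2 of Col-0 after avrB and 201 without array 2 of atgsnor1-1 after avrB; it was also 127 and 30 without array 1 or 2 of untreated Col-0, 14 and 26 without array 1 or 2 of untreated atgsnor1-1, 3 without array 1 of Col-0 after avrB and 5 without array 1 of atgsnor1-1 after avrB. The 355 became 213 and 214 without array 1 or 2 of Col-0 after avrB and 203 without array 1 of sid2 after avrB.

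Of the 76 genes of atgsnor1-1, 15 named genes were followed through the other settings and without each array in turn, save that a gene too dim for the filter that leaves out the lowest 60% has no value there, here AT3G15220. Of the 15, AT5G62360 at -2.01 kept its call wherever it was tested. Those that lost their call at least once were AT4G12490 at 2.35, AT4G23885 at 1.67, AT1G65500 at 1.66, AT3G03790 at 1.60, AT3G29240 at 1.58, AT4G00700 at 1.56, ATERDJ3B at 1.38, AT3G15220 at -3.62, AT1G04040 at -2.50, AT2G10940 at -1.78, AT2G44770 at -1.74, AT3G13740 at -1.56, AT1G29670 at -1.48 and AT3G16370 at -1.45. Of the 14 calls lost at least once, 14 without array 2 of Col-0 after avrB, 13 without array 1 of Col-0 after avrB, 13 without array 1 of atgsnor1-1 after avrB, 12 without array 2 of untreated Col-0, 12 without array 1 of untreated atgsnor1-1, 9 without array 2 of untreated atgsnor1-1, 3 without array 2 of atgsnor1-1 after avrB and 1 without array 1 of untreated Col-0 were lost; the limma adjusted p without these arrays ran from 0.0511 to 0.208.

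Of the 2055 genes of atgsnor1-3, 31 were followed in this way. Of these, 23 were called wherever they were tested, AT3G01830 at 7.44, AT5G51440 at 6.91, AT1G57630 at 6.28, AT2G41730 at 5.42, AT5G52760 at 5.30, AT5G39670 at 5.06, AT5G08240 at 5.04, AT3G13950 at 4.87, AT2G39870 at -5.27, HAT2 at -4.86, AT2G25270 at -4.55, AT4G01130 at -4.32, AT5G42860 at -4.31, AT3G20820 at -4.29, GRX480 at 3.29, PORB at -1.34, AT2G21640 at 4.26, STZ at 2.46, BZIP60 at 2.70, CML38 at 3.62, AT2G31790 at -1.71, BCAT4 at -1.99 and CCR2 at 3.76, and 8 lost their call at least once, AT5G12440 at -4.79, AT4G09890 at -4.47, WRKY53 at 1.39, SGT1A at 1.05, BIK1 at 1.01, WES1 at -3.52, PRK at -1.09 and GR1 at 1.09. The filter that leaves out the lowest 60% removed 12 of the 31, so AT5G51440, AT5G08240, AT2G39870, HAT2, AT2G25270, AT4G01130, AT5G42860, CML38 and CCR2, 9 of the 23, were not tested under it. Of the 8 calls lost at least once, 5 without array 2 of untreated Col-0, 4 without array 1 of Col-0 after avrB, 4 without array 2 of atgsnor1-3 after avrB, 4 without array 1 of untreated atgsnor1-3, 3 without array 2 of untreated atgsnor1-3, 3 without array 2 of Col-0 after avrB, 2 without array 1 of untreated Col-0 and 2 without array 1 of atgsnor1-3 after avrB were lost; the limma adjusted p without these arrays ran from 0.015 to 0.121, with a log2 under 1 in size where it passed.

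Of the 355 genes of sid2, 21 were followed. Calls were kept wherever they were tested by 12 of these, AT3G01830 at 6.39, AT4G39670 at 5.66, AT5G08240 at 5.45, AT1G05340 at 5.07, AT2G32030 at 4.94, AT2G32140 at 4.90, AT1G19960 at -3.17, ORA47 at -2.64, AT5G52810 at 1.81, SGT1A at 1.68, BZIP60 at 1.68 and ATERDJ3B at 1.92, and lost at least once by the other 9, AT3G48640 at 5.62, XTH18 at 4.75, PDF1.2 at -4.77, AT5G25240 at -3.22, AT5G49430 at -2.88, AT5G47455 at -2.88, AT1G22900 at -2.86, AT3G59670 at -2.60 and CCR2 at 2.84. The filter that leaves out the lowest 60% removed 13 of the 21, so AT5G08240, AT1G05340, AT2G32030, AT2G32140 and ORA47, 5 of the 12, were not tested under it. Of the 9 calls lost at least once, 9 without array 1 of Col-0 after avrB, 9 without array 1 of sid2 after avrB, 7 without array 2 of Col-0 after avrB, 7 without array 2 of sid2 after avrB, 7 without array 2 of untreated sid2, 6 without array 2 of untreated Col-0, 6 without array 1 of untreated sid2 and 2 without array 1 of untreated Col-0 were lost; the limma adjusted p without these arrays ran from 0.0526 to 0.2.

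Of 3 tested salicylic acid markers, the difference in response from Col-0 was called for 0 in atgsnor1-1, 2 in atgsnor1-3 and 0 in sid2 (2 in each when adjusted over the list alone). The markers were lower than in Col-0 in untreated atgsnor1-3 and sid2, and after avrB none was called higher than in Col-0 in any mutant. Tested as a list, they ranked towards a more positive response in atgsnor1-1 (camera adjusted p = 0.000661, and adjusted p = 0.0309 with an estimated correlation), atgsnor1-3 (camera adjusted p = 0.0158, and adjusted p = 0.0877 with an estimated correlation; 0.0623 with a pseudocount) and sid2 (camera adjusted p = 0.0384, and adjusted p = 0.1 with an estimated correlation; 0.054 with quantile normalization and 0.267 with a pseudocount). The endoplasmic reticulum chaperone list, of which BZIP60 is a transcription factor, did so in atgsnor1-1 (1 of 3 called; camera adjusted p = 3.51e-05, and adjusted p = 0.0459 with an estimated correlation) and sid2 (2 of 3 called; camera adjusted p = 1.05e-06, and adjusted p = 0.046 with an estimated correlation). In sid2, glutathione S-transferases, U-box ubiquitin ligases and calmodulin-like proteins had adjusted p = 0.0479, 0.0479 and 0.0317 by camera (median log2 of -0.28, 0.55 and 0.89; adjusted p = 0.242, 0.336 and 0.242 with an estimated correlation). In atgsnor1-3, expansins, trichome birefringence-like proteins, serine carboxypeptidase-like proteins and ATG8 autophagy proteins had adjusted p = 0.00643, 0.00498, 0.000463 and 0.011 by camera (median log2 of -1.02, -1.42, -1.31 and 0.51; adjusted p = 0.13, 0.166, 0.0498 and 0.252 with an estimated correlation). Tubulins had adjusted p = 5.68e-05, 0.011 and 0.0479 in atgsnor1-1, atgsnor1-3 and sid2 (median log2 of -0.77, -1.24 and -0.61; adjusted p = 0.292, 0.252 and 0.336 with an estimated correlation). The differences of all 3 mutants are taken from the response of the same Col-0 arrays. A list that moves alike in several mutants is therefore not an independent result in each.

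Untreated atgsnor1-3 and sid2 shared 443 genes lower than in Col-0. Common Col-0 arrays do not account for this, since with no array in common 351 genes were lower in both where independent lists would share 26.8. One wrongly labelled mutant array does not either: with 1 array of each mutant left out, the 4 combinations gave 328 to 388 shared genes against 32.8 to 38.3 for independent lists. Plants of these mutants that were grown or harvested apart from the others could also share such a difference, and this stays open, since the labels give no batch and only 1 gene of the touch list was tested. A biological difference common to both mutants, such as lower salicylic acid signalling in untreated leaves, is open too and was not tested apart from growth.

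Responses to avrB differed from Col-0 in 2055 genes in atgsnor1-3, with larger responses among genes called in both. The median ratio to Col-0 among such genes was 1.56 in atgsnor1-3, but also 1.17 in atgsnor1-1 and 1.31 in sid2. All these ratios use the same Col-0 arrays, which could account for part of each. With no Col-0 array, the median ratio was 1.34 for atgsnor1-3 to atgsnor1-1 and 0.803 for sid2 to atgsnor1-3. The choice between the deposited scaling and quantile normalization does not account for the number of differing responses, as 2002 differed with the latter. Both take the arrays to have like overall signal levels, so an effect of scaling beyond that choice is not excluded. The median ratio was not recomputed with quantile normalization. A lower level before treatment could account for part of the more positive responses, as 46.8% of those genes were lower in untreated atgsnor1-3. For the others it leaves the difference open. The untreated difference is itself a part of the difference between responses, from the same arrays. The share therefore divides up that contrast and cannot test this explanation. Degraded RNA stays open, since the 3' to 5' ratios of control probe sets went different ways in atgsnor1-3 against Col-0 after avrB: GAPDH by -0.0267 with a replicate SD of 0.248, ubiquitin by -0.0503 with 0.188, actin by 0.480 with 0.282, and an earlier actin probe set by -8.68 with 2.21, the last opposite to degradation. The loss of the reductase itself is a candidate explanation that the design holds and that was not tested apart from these.

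The 7 genes higher in all 3 mutants than in untreated Col-0 had a median log2 difference of 2.56. Low values in the untreated Col-0 arrays, which all 3 comparisons share, may account for this: after avrB, where other Col-0 arrays are the control, the median was -0.0270 (range -1.31 to 1.83), and 1 of the 7 was called higher in any mutant. A response of these genes to avrB in Col-0 alone would look the same, and these values do not separate these readings.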

How the results depend on the processing

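The test of the overlap with no array in common was chosen only after the result was seen, and the gene families after the gene names; the other alternatives were planned. Of 105 counts of called genes recomputed under other settings, 91 stayed within 1.5 times, and no call was reversed. In untreated atgsnor1-1 against Col-0 the count of 20 became 10 with no filter, 6 with the lowest 60% left out and 6 with only the compared groups in the fit. With only those groups, it went from 1199 to 782 in untreated atgsnor1-3, from 22 to 63 in atgsnor1-1 after avrB, from 205 to 374 in sid2 after avrB and from 76 to 119 for the difference between responses of atgsnor1-1 and Col-0. In atgsnor1-1 after avrB the count of 22 was 12 with no filter and 11 without a trend. For the difference between responses of atgsnor1-1 and Col-0 it was 42 with no filter, 126 with a pseudocount and 29 without a trend, and for that of sid2 222 in place of 355 without a trend. A pseudocount also moved the split of higher against lower from 12 and 8 to 11 and 14 in untreated atgsnor1-1, from 7 and 15 to 14 and 15 in atgsnor1-1 after avrB, and from 30 and 46 to 65 and 61 for its difference in response. The cause was not tested for any of these.

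With the replicate block, the count in atgsnor1-1 after avrB was 11 in place of 22, and the block moved no other count of called genes by over 1.5 times. The numbers do not pair the arrays: deviations of same-numbered arrays correlated, across genes, at -0.153 to 0.105 over 28 pairs of groups, with a median of -0.002.

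Leaving out 1 array at a time gave 7 to 83 genes in untreated atgsnor1-1 (array 2 of atgsnor1-1 and array 1 of Col-0 left out), 5 to 113 in atgsnor1-1 after avrB (array 2 of Col-0 and of atgsnor1-1), 94 to 146 in sid2 after avrB (array 2 and array 1 of sid2), 1 to 201 for the difference in response of atgsnor1-1 (array 2 of Col-0 and of atgsnor1-1, after avrB) and 203 to 451 for that of sid2 (array 1 of sid2 after avrB and array 1 of untreated Col-0). The responses to avrB ran from 1455 to 1669 genes in Col-0, 2314 to 2635 in atgsnor1-1, 4329 to 4791 in atgsnor1-3 and 2726 to 2887 in sid2.

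Of 75 tests of lists fixed in advance, 27 were called with the preset correlation, 13 with an estimated one, 28 with quantile normalization, 27 with a pseudocount and 27 with the replicate block. Of 315 tests of added families the calls were 46, 3, 41, 57 and 45. The 443 genes lower in both untreated atgsnor1-3 and sid2 became 351 and 279 with no array in common, the latter with atgsnor1-1 as the control of sid2.

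Of 852 results for single genes, 9616 values were recomputed. Under other settings 5393 of 5720 kept their call and 327 lost it, of which 84 with only the compared groups in the fit, 62 without a trend, 57 each with no filter and a pseudocount, 46 with quantile normalization and 21 with the replicate block. With 1 array left out, 3180 of 3896 kept it and 716 lost it. A signal near background limits the size of a difference more than its direction.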

Other observations

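The families below were chosen after the gene names were seen and before any values were tested, and the filter-free test of the mitochondrial stress list was chosen only after its result had been seen. Serine carboxypeptidase-like proteins, enzymes of which some make acyl esters in plant secondary metabolism, were lower in atgsnor1-3 after avrB. Of 15 tested members 8 were lower than in Col-0 (9 when adjusted over the list alone), with a median log2 of -1.22 (camera adjusted p = 2.52e-06, and adjusted p = 0.0127 with an estimated correlation). Without array 2 of atgsnor1-3 after avrB 6 of the 8 kept their call, and without array 2 of Col-0 after avrB 7 did. The largest differences were those of scpl50 at -2.61 ± 0.44, SCPL45 at -2.60 ± 0.54 and scpl46 at -2.42 ± 0.24. Against atgsnor1-1 after avrB, 8 of 15 were lower (camera adjusted p = 2.36e-05, and adjusted p = 0.0216 with an estimated correlation). Of these, 6 kept their call without array 2 of atgsnor1-3 and 7 without array 1 of atgsnor1-1. In the response of atgsnor1-3, 10 of 15 fell (camera adjusted p = 0.000772, and adjusted p = 0.0586 with an estimated correlation). Of these, 9 kept their call without array 2 of untreated atgsnor1-3 or array 1 after avrB. Expansins, which loosen cell walls, were lower in atgsnor1-3 after avrB for 5 of 9 tested members, with EXPB1 at -3.45 ± 0.56 and EXPA8 at -3.40 ± 0.42 (camera adjusted p = 0.00123, and adjusted p = 0.0607 with an estimated correlation).

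U-box ubiquitin ligases, some of which temper defence signalling, rose after avrB for 4 of 6 tested members in each of the 4 genotypes. Their camera adjusted p was 0.0342 in Col-0, 0.00531 in atgsnor1-1, 0.0246 in atgsnor1-3 and 0.0048 in sid2, and with an estimated correlation adjusted p = 0.157, 0.135, 0.156 and 0.111. Calmodulin-like proteins, which sense calcium, rose for 4 of 6 tested members in Col-0, atgsnor1-1 and sid2 and for 3 in atgsnor1-3, with a median log2 of 1.71, 2.83, 3.07 and 2.17 (camera adjusted p = 0.0342, 0.0233, 0.0048 and 0.0241; adjusted p = 0.157, 0.135, 0.111 and 0.148 with an estimated correlation). In Col-0, 3 of the 4 members of each of these 2 families kept their call without array 1 of the untreated leaves or array 1 or 2 after avrB, and in atgsnor1-1 3 of the 4 calmodulin-like proteins did so without array 2 of the untreated leaves or array 1 after avrB.

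Single genes high in atgsnor1-3 after avrB, among them AT2G21640, known as a gene induced by oxidative stress, gave rise to the hypothesis that this mutant may have a larger mitochondrial stress response. A list of 19 genes of that response, without the genes that prompted it, was written before it was tested. It was tested on the same arrays that prompted the hypothesis, so its p-values are no independent support. Of these, 8 were named on the array and 3 passed the filter, with a median log2 of 1.77 against Col-0 after avrB and 1 of them called higher; the camera p was 0.00428, and p = 0.0203 with an estimated correlation. Without the filter, 7 of the 8 genes lay in both atgsnor1-3 arrays after avrB above all other 14 arrays, and 6 were called higher, with a median of 2.96 (range 0.69 to 7.26; camera p = 2.48e-08, and p = 0.00042 with an estimated correlation). The 2 arrays of the transporter gene AT2G04050 stood at 382 and 469 units, those of GSTU25 at 308 and 410, and those of NDB4 at 74.6 and 78.2. In Col-0 after avrB the same genes lay near background, at 2.26 and 3.37, 2.46 and 20.8, and 2.91 and 2.19 units. These genes also answer to other stresses, so the result is no measure of mitochondria.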
